A study of Mus musculus with 57 samples.

How the data were processed

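Genomic DNA from mouse B-lineage cells was assayed by HTGTS-Rep-seq, in which a primer at a JH or Jκ coding end (the bait) amplifies the V(D)J and DJ joins made to that J segment. The series holds 57 samples, of which 8 have no deposited file. The remaining 49 libraries each have a table of V(D)J joins, 41 of them heavy-chain and 8 light-chain, and 15 of the heavy-chain libraries also have a table of DJH joins. Mice were wild type, not immunised and 4 to 6 weeks old, per the labels. Progenitor B (pro-B) cells were sorted from bone marrow as B220-positive, IgM-negative, CD43-positive cells, and splenic resting B cells were taken by bead selection, per the labels' protocols, which name a positive and a negative selection without saying which library used which.

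In the V(D)J tables, V, D and J segments were called per read with Igblast on joined read pairs or on read 1, and only passing reads were kept, per the deposited column description; the version is not stated. Each row is 1 read with its best V, D and J call, its frame and the bases between the segments. The deposited Igblast alignment score of each D hit was read but entered no test. The DJH tables list 1 junction of the JH bait with DH prey per row, with its coordinate, per the file headers. C57BL/6 libraries were aligned to mm9 and 129SVE libraries to mm9 with a 129 heavy-chain insert, per the labels, so V segments carry IGHV names in C57BL/6 and VH names in 129SVE, and each strain was fitted alone. No column holds counts of reads per segment, so rows were tallied here.

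A row was productive when called in-frame without a stop codon, and non-productive when out of frame or in-frame with a stop codon. CDR3 sequences are absent from most tables, so the planned CDR3 length was replaced by the junction length, the bases between the end of V and the start of J. Bases that fit 2 segments (in brackets in the tables) are listed outside the V, D and J columns and were not counted. A distinct junction was a distinct combination of V, D, J and junction bases. DJH joins were assigned to the DH segment that holds their coordinate, and were compared with the V(D)J rows whose DH call matches a segment with a placed position. The share of a segment is its percentage of the rows of its class in a library. Segment positions come from the mm9 annotation and are 1-based.

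Samples were grouped by title. For some mixed-primer and Jκ libraries the title and the label's primer strategy or DNA amount disagree, and the title was used. The comparisons, tests, named segments and lists below were fixed before the data were examined. V usage was compared with limma 3.58.1 (voom weights, lmFit, eBayes, two-sided) in R 4.3.3 on tallied rows per segment, with library size set to the rows of the class, for segments with at least 10 rows in at least 2 libraries, and p was adjusted by Benjamini-Hochberg with a threshold of 0.05. Productive and non-productive columns of a library were fitted with library as a block. The difference of their ratio between splenic and pro-B cells was the interaction term. The JH baits and DNA amounts were compared by a moderated F-test. Values per library (productive share, junction length, DH and domain shares) were compared by two-sided permutation tests, exact within strain for pro-B against splenic cells, within bait for the strains and by sign flips within libraries for DJ against V(D)J joins, and with 100000 resamples across baits. The interaction of class and bait was not planned and was added after the values by class were seen. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

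Named segments were the 10 with the largest rise and the 10 with the largest fall among those past the threshold, with a mean share of at least 0.5% in a group and no overlap between the groups' libraries (for productive against non-productive rows, the same direction in every library; for F-tests, the 10 with the largest range). Always named were IGHV5-2, IGHV2-2, IGHV5-4, IGHV2-3 and IGHV5-6 (D-proximal), IGHV1-26, IGHV1-72, IGHV1-53 and IGHV8-12 (distal), IGHV14-2, IGHV3-6 and IGHV9-3 (middle), and IGHV11-2, IGHV12-3, IGHV7-1 and IGHV6-6 (linked to B-1 cells or natural antibodies). Lists tested with limma's fry were the VH families, the D-proximal domain (families 2 and 5), the middle domain (families 3, 4, 6, 7, 9 to 16), the distal domain (families 1 and 8) and a B-1-linked list (IGHV7-1, IGHV11-1, IGHV11-2, IGHV12-3 and IGHV6-6), B-1 cells being the other B cells a spleen preparation can hold. A CD43-negative selection removes B-1 cells and a B220-positive one need not, so what the splenic shares of these segments mean depends on the selection, which the labels do not give per library. DH families were DFL16 (IGHD1), DSP2 (IGHD2), DST4 (IGHD3) and DQ52 (IGHD4).

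Intervals are exact Clopper-Pearson at 95%, and the limit for a share of 0 is 3 rows of the total. Rows are PCR reads without molecular identifiers, so both cover counting error only. Replicates of every group differed by more than counting error of independent rows would give; rows are not independent, so this alone does not show a difference between mice. The fits were tested on simulated data in which 30 segments were changed, over 10 draws. In the productive comparison of pro-B and splenic cells, 66.7% of 2-fold changes were recovered in C57BL/6 and 81.5% in 129SVE. In the non-productive comparison the recovery was 36.4% and 34.5%, and for 3-fold changes 81.6% and 85.8%.

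Titles number the mice. In the JH bait sets, libraries of different baits with the same mouse number were read as pairs from the same animal, though the labels do not say so. Their deviations from the group means correlated at r = 0.0487 to 0.433 in C57BL/6 and at r = -0.389 to 0.534 in 129SVE, where the 2 negative values both involved JH4 replicate 3, which correlated at r = 0.136 to 0.476 with the replicate 1 libraries, so the reading is open there. Between pro-B and splenic libraries the titles do not say that marrow and spleen came from the same mouse, r was -0.0845 to 0.122 for C57BL/6 productive rows, and the numbers were not read as pairing. Read identifiers placed the libraries in 6 sequencing runs, called A to F. All 129SVE pro-B and splenic libraries of that comparison were in run A, whereas those of C57BL/6 were in runs A, C and E. The C57BL/6 bait and DNA amount libraries were all in run E.

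Alternatives were limma-trend on log2 percentages with pseudocounts of 0.01 and 0.1%, no filter, centring on the median segment, distinct junctions, rows with a single V allele or a single DH called, the replicate number as a block, a splenic group enlarged by the splB_JH4 libraries, each row class alone, mice other than mouse 1, DH assignment within 10 bp of the coding end, JH4-bait libraries alone, and each library left out. Added after the data were seen were the sequencing run as a block, run A alone, 1 run per strain, DJ joins within 60 bp of a DH segment, non-productive V(D)J rows against DJ joins, every DH call of the V(D)J rows against DJ joins, labels moved within mouse numbers for B-1-linked segments with the JH1 bait, signs flipped by mouse for DJ against V(D)J joins, thinning to 6961 rows, and thinning of productive to non-productive rows.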

Results

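The repertoires of rearranged immunoglobulin genes in pro-B and splenic resting B cells of C57BL/6 and 129SVE mice were read from genomic DNA. Genomic DNA carries non-productive as well as productive joins, so both can be compared in the same library. The tables held 2102040 V(D)J rows, 1 per read, in 49 libraries, with 6961 to 190998 rows and 628 to 53974 distinct junctions per library. The 15 DJH tables held 6453 to 61954 rows each. The libraries fell into 25 groups, and 10 of these groups had a single library. Pro-B cells were read with the JH4 bait in 3 mice of each strain. Splenic B cells were read with the same bait in 3 C57BL/6 and 2 129SVE mice, and with baits at JH1, JH2, JH3 and JH4 in 2 or 3 mice per bait and strain. Further libraries varied the DNA amount, mixed the bait primers, or read the κ light chain from Jκ baits. The bait J segment was called in at least 99.7% of the rows of every library. A single V allele was listed in 91.1% to 99.0% of the rows.

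The first comparison asked how the repertoire differed between pro-B cells, in which VH to DJH joining takes place, and splenic B cells, which have passed selection on the assembled receptor. Productive joins made up a smaller share of the rows in pro-B than in splenic cells. In 129SVE the share was 41.3% ± 1.73 (SD, n = 3) in pro-B and 73.0% ± 1.81 (SD, n = 2) in splenic cells. In C57BL/6 it was 64.9% ± 7.16 (SD, n = 3) and 73.2% ± 0.873 (SD, n = 3). Every pro-B library lay below every splenic library of its strain. The mean difference within strains was -20.0 percentage points (exact permutation p = 0.005, the smallest that 200 arrangements allow), and within sequencing run A it was -24.3 points (exact permutation p = 0.0333, the smallest of 30 arrangements). The difference was larger in 129SVE by 23.4 points, which missed the threshold when tested itself (exact permutation p = 0.06). Productive junctions of pro-B cells were longer by 0.725 nt (exact permutation p = 0.01), at 17.3 ± 0.276 nt against 16.8 ± 0.2 nt in C57BL/6 and 17.3 ± 0.183 nt against 16.2 ± 0.144 nt in 129SVE. In 129SVE 3 of 3 pro-B libraries lay above every splenic library, and in C57BL/6 2 of 3.

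**Figure D1:**
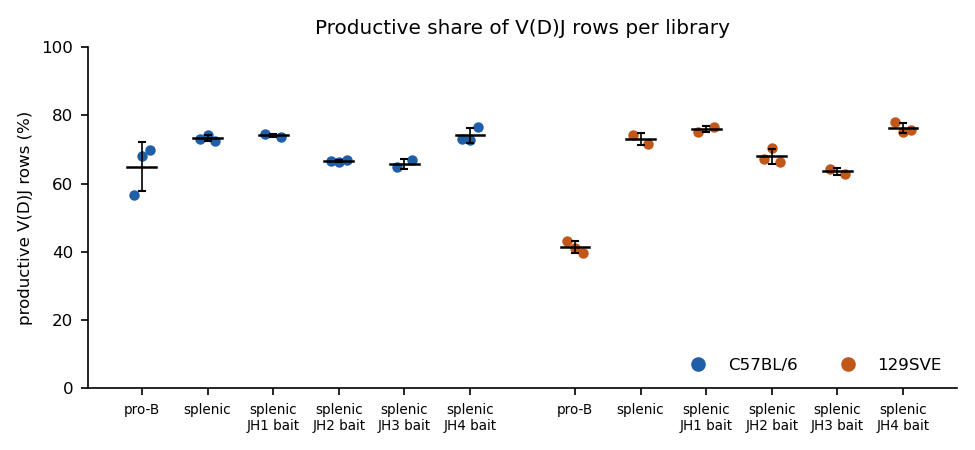
Productive V(D)J rows as a percentage of all V(D)J rows per library (y axis), by cell type, bait and strain (x axis); points are libraries, bars are means and error bars SD. The 129SVE pro-B libraries lay between 39.6% and 43.1%, the C57BL/6 pro-B libraries between 56.7% and 69.9%.

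In 129SVE, the productive JH4 joins of pro-B cells held more of VH5-2 and of B-1-linked segments. Pro-B cells were not read with other baits, and splenic shares of some of these segments depended on the bait. VH11-2 took 0.974% ± 0.315 of splenic productive rows with the JH1 bait (SD, n = 2). VH5-2, a D-proximal segment known as VH81X, took 4.01% ± 0.308 (SD, n = 3) of productive rows in pro-B and 0.405% ± 0.224 (SD, n = 2) in splenic cells, a 10.8-fold difference (log2 3.43, adjusted p = 4.1e-05). VH11-2, whose products are typical of B-1 cells that bind phosphatidylcholine, took 0.493% ± 0.0873 and 0.0240% ± 0.0166 (log2 4.45, adjusted p = 0.002). VH12-3, with the same known specificity, took 0.271% ± 0.102 and 0.00907% ± 0.00161 (log2 4.74, adjusted p = 0.015). VH11-1 took 0.133% in pro-B cells, and none of 99419 splenic productive rows, which allows up to 0.00302%. VH4-2 (0.756% ± 0.11 against 0.161% ± 0.0195), VH8-2 (0.523% ± 0.121 against 0.0714% ± 0.00283), VH1-11 (0.628% ± 0.152 against 0.0829% ± 0.0387), VH7-1 (1.55% ± 0.307 against 0.6% ± 0.0946) and VH15-2 (0.868% ± 0.212 against 0.329% ± 0.0673) were also higher in pro-B cells. VH13-2, VH10-1, VH10-3 and VH5-12 completed the named segments that were higher, with log2 1.68, 0.98, 1.23 and 1.2. Splenic cells held more VH3-2 (3.58% ± 0.125 against 2.17% ± 0.121, adjusted p = 0.0073), VH5-17 (2.61% ± 0.38 against 1.45% ± 0.193), VH1-4 (2.55% ± 0.277 against 1.25% ± 0.438) and VH1-80 (1.04% ± 0.16 against 0.515% ± 0.137). VH14-1, VH3-6 and VH1-14 were also lower in pro-B cells, with log2 -1.15, -0.76 and -0.64. In all, 24 of 124 segments were higher and 8 lower in pro-B cells, and 48 had an unadjusted p under 0.05. Among segments with a mean share of at least 0.5% in a group, 43 did not overlap between the groups' libraries. Chance gives 20% of the segments of that share, not of all 124. Without pro-B replicate 1 the number past the threshold fell to 5, and without pro-B replicate 2 to 21.

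Of the lists in 129SVE productive rows, the B-1-linked segments were the clearest group, with 4 of 5 higher in pro-B cells, and 4 when adjusted over the list alone (median log2 4.45, fry adjusted p = 0.00435). Family 11 had 2 of 2 higher (fry adjusted p = 0.00435). The D-proximal domain had 6 higher and 1 lower of 36, or 2 and 1 adjusted over the list alone (fry adjusted p = 0.239). The middle domain had 9 higher and 3 lower of 30, or 11 and 7 adjusted over the list alone (fry adjusted p = 0.129, with a median log2 of -0.02 and a mean of 0.79, of opposite sign). The distal domain had 9 higher and 4 lower of 58, or 5 and 2 adjusted over the list alone (fry adjusted p = 0.122). Of the other families, none passed the directional test (fry adjusted p of at least 0.0647).

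In C57BL/6 the same comparison gave fewer segments, and IGHV5-2 and IGHV12-3 were again among those higher in pro-B cells. IGHV15-2 took 0.876% ± 0.0294 (SD, n = 3) of productive rows in pro-B and 0.224% ± 0.0713 (SD, n = 3) in splenic cells (log2 2.06, adjusted p = 0.0041). IGHV5-2 (mm9 chromosome 12, 114816715 to 114817201) took 1.12% ± 0.827 and 0.206% ± 0.0524 (log2 2.07, adjusted p = 0.012), and IGHV12-3 took 0.524% ± 0.541 and 0.0728% ± 0.0349 (log2 2.31, adjusted p = 0.031). The IGHV12-3 value rested most on pro-B replicate 1, with 1.15% against 0.185% and 0.239% in the other pro-B libraries; without it the log2 change was 1.86 (adjusted p = 0.028). Without splenic replicate 1, 2 or 3 IGHV12-3 did not pass, at 2.83, 1.71 and 2.42, nor did IGHV5-2 without splenic replicate 1 or 2, at 1.91 and 1.93, or IGHV15-2 without splenic replicate 1, at 1.73. IGHV5-12 (1.27% ± 0.315 against 0.668% ± 0.0457), IGHV10-1 (2.8% ± 0.148 against 2.02% ± 0.245) and IGHV1-81 (4.01% ± 0.782 against 2.63% ± 0.192) were also higher in pro-B cells. The distal segments IGHV1-52 (0.482% ± 0.101 against 1.31% ± 0.27, log2 -1.57, adjusted p = 0.01), IGHV1-80 (0.953% ± 0.285 against 1.98% ± 0.393), IGHV1-26 (3.90% ± 0.436 against 5.60% ± 0.411) and IGHV1-82 (2.14% ± 0.178 against 3.04% ± 0.168) were lower. IGHV11-2 stood at 0.0696% ± 0.0343 and 0.0920% ± 0.0308 and did not pass the test (adjusted p = 0.81). In all, 6 of 98 segments were higher and 4 lower, and 28 had an unadjusted p under 0.05. Among segments with a mean share of at least 0.5% in a group, 23 did not overlap between groups. Chance gives 10% of the segments of that share, not of all 98. With the sequencing run as a block, the contrast rests on run A alone, with pro-B replicate 1 against splenic replicates 1 and 2. Its count is therefore not given. Leaving out pro-B replicate 1 gave 25 segments past the threshold, splenic replicate 1 gave 0 and splenic replicate 2 gave 3. Most IGHV5-2 and IGHV5-12 rows in this strain listed more than a single V allele. Among the rows with 1 allele, 25 of 322 IGHV5-2 rows in pro-B and 29 of 168 in splenic cells, its log2 change was -0.00335, and that of IGHV5-12 was -0.69.

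Among the C57BL/6 lists in productive rows, the middle domain moved up in pro-B cells, with 3 of 27 higher, also 3 adjusted over the list alone (median log2 0.19, fry adjusted p = 0.0444). The domains were set by family and not by position. Of the 3, IGHV10-1 and IGHV15-2 lie among IGHV1 segments in mm9, so this is not a result about a stretch of the locus. Of the distal domain, 1 was higher and 4 lower of 55, or 1 and 3 adjusted over the list alone (fry adjusted p = 0.350). The D-proximal domain had 2 higher of 16, or 2 higher and 1 lower adjusted over the list alone (fry adjusted p = 0.551). The B-1-linked list had 1 higher of 4, or 2 adjusted over the list alone (fry adjusted p = 0.192). Of the families, none passed the directional test, family 4 coming closest (fry adjusted p = 0.0504). Centring on the median segment moved the median log2 change from 0.03 to -0.14 in this strain and from 0.03 to -0.08 in 129SVE. The lists were not tested with centring. The middle domain held 27.9% ± 3.26 of C57BL/6 productive rows in pro-B and 23.5% ± 0.704 in splenic cells. Over both strains, 0 of 6 domain shares passed the exact permutation test. The largest was the distal productive share, lower in pro-B cells by -3.13 points (exact permutation p = 0.05, adjusted p = 0.30).

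Non-productive joins, which cannot be selected for their protein, showed no segment past the threshold between pro-B and splenic cells. VH5-2 took 13.2% ± 1.3 (SD, n = 3) of 129SVE non-productive rows in pro-B and 15.4% ± 10.3 (SD, n = 2) in splenic cells (log2 -0.04, adjusted p = 0.97), and without splenic replicate 3 the change was 0.68 (adjusted p = 0.027). VH2-2 took 6.52% ± 0.71 and 6.96% ± 3.77, VH11-2 1.06% ± 0.109 and 1.02% ± 0.561, and VH12-3 0.835% ± 0.238 and 0.658% ± 0.0818. In C57BL/6, IGHV5-2 took 7.74% ± 1.92 and 6.05% ± 0.283 (SD, n = 3 each; log2 0.29, adjusted p = 0.60). By limma, 0 of 134 segments passed in 129SVE, with 9 at an unadjusted p under 0.05, and 0 of 118 in C57BL/6, with 12. Among segments with a mean share of at least 0.5% in a group, libraries did not overlap in 13 in 129SVE and 11 in C57BL/6. Chance gives 20% and 10% of the segments of that share, not of all 134 and 118. The B-1-linked list gave a fry adjusted p of 0.769 in 129SVE and 0.639 in C57BL/6, the D-proximal domain 0.684 and 0.699, the middle domain 0.999 and 0.639, and the distal domain 0.808 and 0.639. The median log2 change moved with centring from 0.17 to -0.05 in 129SVE and from -0.14 to -0.00 in C57BL/6. Single libraries mattered: leaving out splenic replicate 3 or 2 of 129SVE gave 3 and 1 segments, and leaving out pro-B replicate 3 of C57BL/6 gave 3. With run as a block, the C57BL/6 contrast rests on run A alone, with pro-B replicate 1 as its only pro-B library, so its count supports no call.

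Within the same libraries, read with the JH4 bait, the productive repertoire differed from the non-productive one in many segments. In both cell types the D-proximal VH5-2 and the B-1-linked VH11-2 took less of the productive rows. Other B-1-linked segments did not all follow, as IGHV6-6 took 1.36% of productive and 0.854% of non-productive rows in C57BL/6 pro-B cells (adjusted p = 0.19). In C57BL/6 splenic cells, IGHV5-2 took 6.05% ± 0.283 of non-productive and 0.206% ± 0.0524 of productive rows (SD, n = 3; log2 -4.99, adjusted p = 3.6e-61), IGHV12-3 1.94% ± 0.0567 and 0.0728% ± 0.0349 (log2 -4.85), IGHV11-2 1.27% ± 0.237 and 0.0920% ± 0.0308 (log2 -3.88), and IGHV7-1 2.16% ± 0.772 and 0.619% ± 0.235 (log2 -1.80). The distal IGHV1-26 rose from 2.57% ± 0.656 to 5.60% ± 0.411 (log2 0.98, adjusted p = 1.8e-17), IGHV1-82 from 1.29% ± 0.081 to 3.04% ± 0.168, and IGHV1-80 from 0.687% ± 0.144 to 1.98% ± 0.393. In C57BL/6 pro-B cells, IGHV5-2 fell from 7.74% ± 1.92 to 1.12% ± 0.827 (log2 -3.16, adjusted p = 0.0017) and IGHV11-2 from 1.07% ± 0.309 to 0.0696% ± 0.0343 (log2 -3.77), and IGHV1-81 rose from 1.31% ± 0.224 to 4.01% ± 0.782 (log2 1.5). In 129SVE pro-B cells, VH5-2 fell from 13.2% ± 1.3 to 4.01% ± 0.308 (log2 -1.71, adjusted p = 5.2e-11), VH2-2 from 6.52% ± 0.71 to 2.83% ± 0.291 (log2 -1.19) and VH11-2 from 1.06% ± 0.109 to 0.493% ± 0.0873 (log2 -1.11). In 129SVE splenic cells (n = 2), VH5-2 fell from 15.4% ± 10.3 to 0.405% ± 0.224 (log2 -5.21, adjusted p = 4e-37), and VH1-80 rose from 0.191% ± 0.102 to 1.04% ± 0.16 (log2 2.43). With 2 libraries the fit leaves a single residual degree of freedom per segment. Its p-values, and those of the groups of 3, rest largely on variance pooled across segments and do not measure the spread between mice of a segment.

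The number of segments that differed between the classes was 36 of 107 in pro-B cells of C57BL/6 (16 higher and 20 lower in productive rows; 58 unadjusted) and 95 of 119 in splenic cells (44 and 51; 96 unadjusted). In 129SVE it was 60 of 129 in pro-B cells (37 and 23, with 74 unadjusted) and 84 of 136 in splenic cells (43 and 41, with 86 unadjusted). The 129SVE splenic count rests on 2 libraries and could not be checked by leaving out a library. Some segments were absent from productive rows. IGHV3-2 had 0 of 38548 productive rows in C57BL/6 pro-B and 0 of 88804 in splenic cells, which allows up to 0.00778% and 0.00338%, against 0.658% and 1.09% of non-productive rows. Centring moved the median log2 change from 0.29 to 0.43 and from 0.09 to 0.56 in C57BL/6 pro-B and splenic cells. In 129SVE it moved from 0.43 to 0.28 and from 0.44 to 0.31. Without pro-B replicate 2 no segment passed in C57BL/6 pro-B cells by limma, and without replicate 3 the count was 23. In 129SVE pro-B cells it was 37 without replicate 1 and 26 without replicate 2.

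With the JH4 bait, the loss of these segments from the productive class was itself larger in splenic than in pro-B cells in 129SVE. The log2 ratio of productive to non-productive shares was lower in splenic cells by -3.53 for VH5-2 (adjusted p = 4.1e-18), -4.24 for VH11-2 (adjusted p = 3e-06), -4.42 for VH12-3 (adjusted p = 0.00062) and -1.29 for VH7-1 (adjusted p = 0.0044), and higher by 1.97 for VH1-80 (adjusted p = 0.0049). In all, 4 of 138 segments were higher and 16 lower (34 unadjusted). Among segments with a mean share of at least 0.5% in a row class, 30 did not overlap, where chance gives 20% of the segments of that share. Without pro-B replicate 1 the count was 13, and without pro-B replicate 2 it was 12. In C57BL/6, limma called 0 of 121 segments (21 unadjusted), with IGHV5-2 at -1.84 (adjusted p = 0.058), IGHV12-3 at -2.57 (adjusted p = 0.15) and IGHV11-2 at -0.08 (adjusted p = 0.92). Of the segments with a mean share of at least 0.5% in a row class, 28 did not overlap there, where chance gives 10%. Without pro-B replicate 1, 9 passed. Centring moved the median from -0.26 to -0.00 in C57BL/6, and 4 segments then passed. Whether the strains differ in this respect was not tested, since their segments were fitted apart.

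**Figure D2:**
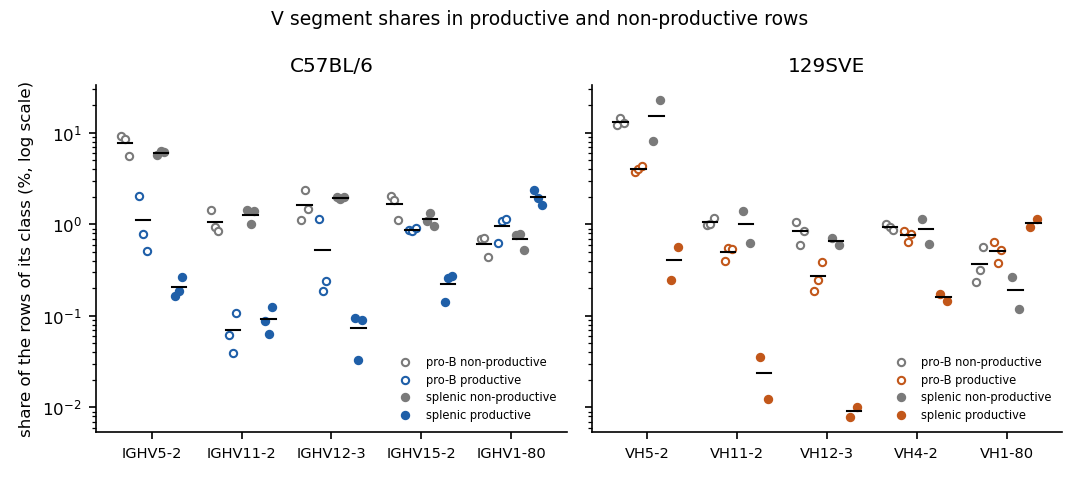
Share of V segments (%, log scale, y axis) among the non-productive and productive rows of pro-B and splenic libraries, for 5 segments per strain (x axis); points are libraries and bars are means. In 129SVE, VH5-2 took 4.01% of productive rows in pro-B and 0.405% in splenic cells, against 13.2% and 15.4% of non-productive rows.

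DH shares over the rows of both classes together also differed between the cell types. The classes were not compared apart, and the productive share differed between the cell types. A different mix of the classes therefore cannot be told apart from different DH use. Pro-B rows held more of IGHD1-1, at 32.9% ± 1.32 against 30.3% ± 0.892 in C57BL/6 and 19.4% ± 0.189 against 15.5% ± 5.04 in 129SVE, a mean difference of 3.26 points (exact permutation p = 0.005, adjusted p = 0.0217). IGHD2-1 was lower in pro-B cells by -1.88 points, IGHD2-4 by -1.53 points (adjusted p = 0.0217 each) and IGHD4-1, the JH-proximal DQ52 segment, by -1.52 points (adjusted p = 0.0325). Every pro-B library lay beyond every splenic library of its strain for IGHD1-1, and 4 of 13 segments passed. By family, DFL16 was higher by 3.48 points (adjusted p = 0.02), DSP2 lower by -1.78 points (adjusted p = 0.0467) and DQ52 lower by -1.52 points (adjusted p = 0.02), while DST4 did not pass (-0.498 points, adjusted p = 0.24). Without splenic replicate 3 of 129SVE, which held 11.9% of IGHD1-1 against 19.1% in replicate 2, the IGHD1-1 difference fell to 1.48 points (adjusted p = 0.0813), and without replicate 2 it was 5.04 points. Within run A, IGHD1-1 was higher by 3.52 points (exact permutation p = 0.0333) and no segment or family passed after adjustment, with 30 arrangements. With a single DH called, no segment and 1 family passed, and IGHD2-4 and DSP2 stood at 0.000773 and 0.0313 points. Leaving out any 129SVE library or C57BL/6 splenic replicate 1 or 3 gave 0 segments, and leaving out any 129SVE pro-B library or splenic replicate 3 gave 0 families. Fewer arrangements remain then, and the differences of IGHD2-1 (-2.14 to -1.61 points), IGHD2-4 (-1.73 to -1.33) and IGHD4-1 (-1.74 to -1.26) stayed of similar size, so for these the lost calls do not show a smaller effect. DSP2 stood at -0.824 points without splenic replicate 3 of 129SVE, and DFL16 ran from 2.10 to 4.86 points.

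The next comparison asked whether the repertoire read from a JH bait depends on the JH segment joined. It did, for the productive share, for DH shares and for single V segments. DH shares were taken over both row classes together, so the mix of classes by bait was not separated from DH use. Productive rows were fewer with the JH2 bait (66.5% ± 0.339 in C57BL/6, 67.9% ± 2.14 in 129SVE, n = 3 each) and the JH3 bait (65.8% ± 1.39 and 63.6%, n = 2 each) than with JH1 (74.1% ± 0.523 and 75.9%, n = 2 each) and JH4 (74.1% ± 2.15 and 76.3%, n = 3 each). The permutation p was 1e-05, the smallest that 100000 resamples give, with an adjusted p of 2e-05. Productive junctions were longest with JH3, at 17.1 nt and 16.5 nt, against 16.6 nt and 16.2 nt with JH4 (permutation adjusted p = 0.0195). Without JH3 replicate 2 of C57BL/6, or without either JH3 library of 129SVE, junction length no longer passed and 1 of these 2 values did. IGHD1-1, a DFL16 segment far from the JH cluster, took 46.7% ± 3.91 and 26.4% ± 2.48 of the rows with JH1 and 26.1% ± 0.306 and 14.1% ± 0.352 with JH3 in C57BL/6 and 129SVE. IGHD2-4 was higher with JH3, at 17.3% ± 0.701 and 17.6%, than with JH1, at 9.08% ± 0.0421 and 9.11%. DQ52, the DH segment next to JH1 (IGHD4-1, mm9 chromosome 12, 114668739 to 114668749), was highest with JH2, at 10.8% ± 1.36 and 13.0% ± 1.90, and lowest with JH4, at 6.29% ± 0.597 and 5.94%. By the permutation test 12 of 13 DH segments and 4 of 4 families passed; IGHD2-1 did not (adjusted p = 0.110).

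Among V segments, IGHV11-2 (mm9 chromosome 12, 115286452 to 115286915) stood out with the JH1 bait. It took 1.21% ± 0.0147 of all C57BL/6 rows with JH1 (n = 2), against 0.445% ± 0.0487, 0.473% ± 0.00863 and 0.391% ± 0.144 with JH2, JH3 and JH4 (adjusted p = 3.2e-05). In 129SVE, VH11-2 took 1.04% ± 0.305 against 0.469% ± 0.106, 0.450% ± 0.0465 and 0.290% ± 0.0493 (adjusted p = 0.044). IGHV10-1 was highest with JH4, at 2.17% ± 0.418 against 1.03% ± 0.134 with JH2, IGHV8-12 was highest with JH1, at 1.99% ± 0.108 against 1.01% ± 0.079 with JH3, and IGHV7-3 ran from 0.531% ± 0.0544 with JH3 to 1.40% ± 0.0661 with JH4. IGHV1-26 was highest with JH3, at 5.31% ± 0.0757 against 3.60% ± 0.343 with JH4. Over all rows IGHV5-2 was also highest with JH3, at 2.46% ± 0.0236 against 1.63% ± 0.0526 with JH1. In productive rows the order was reversed, at 0.370% and 0.312% in the JH1 libraries against 0.274% and 0.244% in the JH3 libraries. JH3 libraries held a larger share of non-productive rows, in which IGHV5-2 is frequent, so its all-row values mix both classes. In all, 29 of 126 segments passed in C57BL/6 (45 unadjusted) and 1 of 147 in 129SVE (38 unadjusted). With the mouse number of the titles as a block the counts were 46 and 7.

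When the classes were taken apart, segments passed across the baits in productive rows and not in non-productive rows. Taken alone, productive rows gave 47 of 105 segments in C57BL/6 and 29 of 129 in 129SVE (58 and 46 unadjusted), and non-productive rows gave 0 of 123 and 0 of 146 by limma (8 and 10 unadjusted). Thinned to the number of non-productive rows, productive rows still gave 44 and 25 (medians of 10 draws). The class-by-bait interaction, tested after these counts were seen, passed for 32 of 125 segments in C57BL/6 and 33 of 146 in 129SVE (48 and 52 unadjusted). IGHV7-1 took 1.01% ± 0.196 of productive rows with JH1, 0.193% ± 0.0363 with JH2, 0.387% ± 0.0749 with JH3 and 0.748% ± 0.124 with JH4 (interaction adjusted p = 1.1e-07), against 1.74% to 1.88% of non-productive rows. IGHV2-2 took 1.34% ± 0.242, 1.04% ± 0.0622, 1.66% ± 0.00689 and 2.36% ± 0.586 of productive rows. IGHV11-2 took 1.14% ± 0.142 with JH1 and 0.0758% to 0.110% with the other baits (interaction adjusted p = 5.7e-06). Of 105 segments named alike in both strains and tested in both, 26 passed the interaction in C57BL/6 and 27 in 129SVE, and 11 in both, where 6.69 would be expected from independent lists (exact hypergeometric test, one-sided p = 0.0268). That test takes all 105 segments as independent and equally likely to pass. Segments frequent in both strains pass more easily in both, so the overlap alone does not show a shared effect of the bait. For 10 of the 11 the bait with the highest productive share was the same. Single libraries mattered for the counts over all rows. In C57BL/6 the count was 19 without JH2 replicate 1 or 3 or JH4 replicate 1. In 129SVE it was 0 without JH3 replicate 3 or any JH4 library, 2 without JH1 replicate 1 or JH2 replicate 2, and 8 without JH1 replicate 2. With mice other than mouse 1 the counts were 2 and 11.

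**Figure D3:**
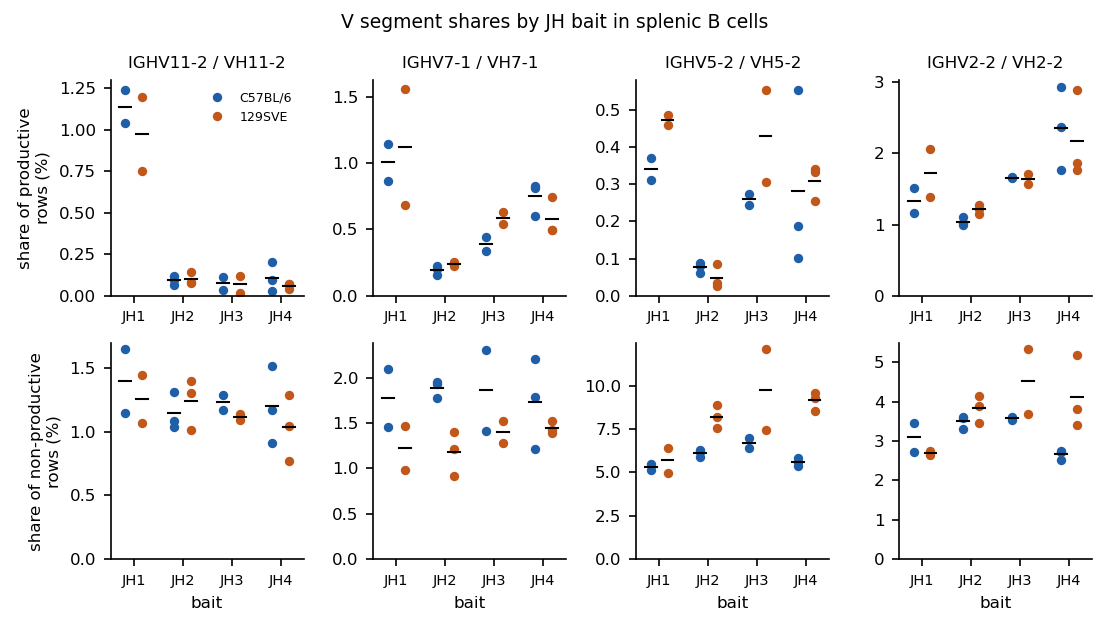
Share of 4 V segments among productive rows (%, upper panels) and non-productive rows (%, lower panels) of splenic libraries by JH bait (x axis); points are libraries, colours are strains and bars are means. IGHV11-2 took 1.14% of C57BL/6 productive rows with JH1 and 0.0758% to 0.110% with the other baits.

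DJH joins lie on alleles that have not joined a V segment, and were compared with the V(D)J rows of the same 15 libraries to ask whether DH use changes when a V is joined. DQ52 took 10.5% ± 4.39 of DJ joins and 7.53% ± 2.78 of V(D)J rows (SD, n = 15), a 1.40-fold difference seen in 15 of 15 libraries (exact sign-flip permutation p = 6.1e-05, the smallest of 32768 flips; adjusted p = 0.0002). IGHD2-3 was lower in DJ joins, at 8.37% ± 1.67 against 11.4% ± 1.13, in 15 of 15 libraries (adjusted p = 0.0002). IGHD2-7, called IGHD2-2 in 129SVE, took 3.42% ± 1.00 and 4.69% ± 0.588, and was higher in DJ joins in 1 library (adjusted p = 0.00031). Equal mouse numbers in the bait sets, and splenic libraries that share more than 10 long junctions with a bait library, were read as the same mouse, so the 15 libraries stand for 10 mice at most. With signs flipped by mouse, a test added after the data were seen, DQ52 and IGHD2-3 (adjusted p = 0.00651 each, the smallest that 1024 flips allow for them) and IGHD2-7 (adjusted p = 0.00977) still passed. The V(D)J shares in this comparison cover the calls of DH segments with a placed position. DSP2 as a family took 47.7% ± 11.9 and 52.3% ± 9.15 (adjusted p = 0.0448) and DST4 3.13% ± 1.60 and 4.76% ± 3.03 (adjusted p = 0.0265), whereas DFL16, at 37.8% ± 8.66 and 34.8% ± 6.82, did not pass (adjusted p = 0.0965). In C57BL/6 with the JH4 bait, the DST4 segment IGHD3-1 took 0.00328% of DJ joins (n = 6). It took 2.29% of the DH calls of V(D)J rows in the JH4 bait set. IGHD3-2 took 3.89% and 3.76%. The DST4 difference thus cannot be told apart from how DH was called. By mouse, DSP2 and DST4 no longer passed (adjusted p = 0.153 and 0.148). In all, 6 of 10 values passed by library and 4 by mouse, counting DQ52 as a family and as its only segment. Over every DH call, an alternative chosen after the data were seen, 7 passed by library and 6 by mouse. DST4 then took 7.8% ± 1.64 of V(D)J rows (difference -4.66 points, adjusted p = 0.0002, by mouse 0.00651), DQ52 differed by 3.80 points, and DSP2 no longer passed (adjusted p = 0.278). IGHD1-1 rose from 3.44 points (adjusted p = 0.068) to 6.88 points (adjusted p = 0.000916, by mouse 0.0234), and DFL16 differed by 4.05 points (adjusted p = 0.0394, by mouse 0.215). Calls without a placed position cannot occur among DJ joins. Counting them raises the V(D)J share of DST4 and lowers that of every placed segment. The values over every DH call therefore do not by themselves show changed DH use. Against non-productive V(D)J rows alone, also chosen after the data were seen, DQ52 differed by 5.69 points (adjusted p = 0.000305) and IGHD2-3 by -2.56 points (adjusted p = 0.00229). DSP2 then differed by -9.45 points (adjusted p = 0.00229, by mouse 0.0391) and IGHD2-4 by -2.36 points (adjusted p = 0.0206, by mouse 0.184). DST4 (-0.214 points, adjusted p = 0.666) and IGHD2-7 (-0.442 points, adjusted p = 0.217) no longer passed. DH was located by coordinate in DJ joins and by sequence in V(D)J rows, where DSP2 segments resemble one another. DQ52 is 11 bp long, against 16 to 23 bp for the segments of the other families. V(D)J rows without a DH call, 5.35% to 8.19% in these libraries, were left out. Missed DQ52 calls in V(D)J rows therefore cannot be told apart from lower DQ52 use. With V(D)J rows that list a single DH, DQ52 turned to -1.93 points, because DQ52 keeps 99.8% of its rows under that choice and DSP2 34.8%.

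By bait, DQ52 took 18.4% ± 0.0921 of C57BL/6 DJ joins with JH2 (n = 2), 12.6% with JH3, 10.2% with JH1 (n = 1 each) and 8.36% ± 1.2 with JH4 (n = 6). In 129SVE it took 17.9% with JH1 (n = 1) and 7.63% ± 2.42 with JH4 (n = 4). Pro-B libraries were read with JH4 alone and made up 3 of these 6 and 1 of these 4. In splenic libraries alone, DQ52 took 9.23% ± 0.683 with JH4 in C57BL/6 and 8.65% ± 1.59 in 129SVE (n = 3 each). DFL16 took 56.8% of C57BL/6 splenic DJ joins with JH1 and 40.0% ± 3.21 with JH4, and 39.8% and 28.0% ± 1.52 in 129SVE. These values by bait were not tested.

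**Figure D4:**
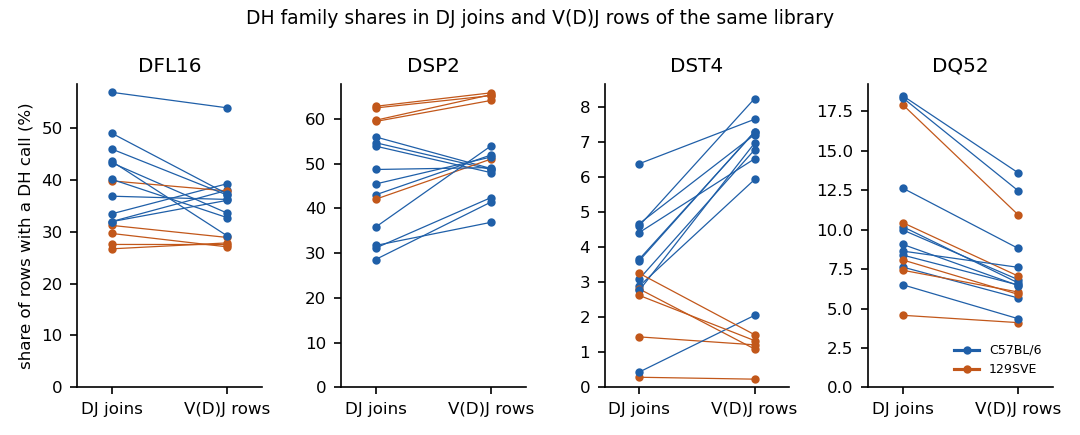
Share of 4 DH families (%, y axis) among the DJ joins and the V(D)J rows of the same library with a call of a placed DH segment; each line joins the values of 1 library and colours are strains. DQ52 was higher in DJ joins in 15 of 15 libraries, with means of 10.5% and 7.53%.

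Between the strains, splenic libraries of the 4 baits (n = 10 each) differed in most family and DH shares and not in the productive share. The distal family VH1 took 55.4% ± 3.26 of C57BL/6 rows and 38.8% ± 1.66 of 129SVE rows. The D-proximal families VH5 and VH2 took 9.60% ± 0.982 and 4.90% ± 0.989 in C57BL/6, and 15.5% ± 1.14 and 10.9% ± 1.58 in 129SVE. VH3 and VH9 were also lower in C57BL/6, at 4.39% and 3.71% against 7.86% and 6.79%. The exact permutation p of each of these was 0.000139, the smallest of 14400 arrangements. VH7 (2.17% and 2.05%, adjusted p = 0.665) and VH14 (4.67% and 4.57%, adjusted p = 0.609) did not pass. IGHD1-1 took 33.7% ± 7.61 and 19.6% ± 4.36, IGHD2-1 7.45% ± 0.63 and 11.6% ± 0.757, and IGHD2-14, which the annotation does not place in C57BL/6, 0.928% ± 0.302 and 11.2% ± 1.32. The productive share was 70.2% ± 4.32 and 71.2% ± 5.64 (difference -0.791 points, exact permutation p = 0.293). In all, 28 of 34 values passed, made up of 13 of 16 VH families, 12 of 13 DH segments and 3 of 4 DH families. The annotation also does not place IGHD1-2, IGHD1-3, IGHD2-10 and IGHD3-3 in C57BL/6, so their shares there are shares of sequence calls. Equal mouse numbers were read as the same animal, so the 10 libraries of a strain stand for 3 mice and are not independent; permuting 3 against 3 mice allows no p under 0.1. The bait libraries of the strains were sequenced in different runs. Within run A, 2 C57BL/6 and 3 129SVE splenic libraries with a JH4 bait held 55.2% to 56.1% and 32.2% to 38.8% of VH1, and 1.02% to 1.07% and 12.4% to 13.1% of IGHD2-14. There, 28 of the 28 values kept their direction and 23 did not overlap between strains, so run alone does not account for those 23. The strains were aligned to different references, so strain and reference cannot be told apart.

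The number of distinct junctions read rose with the DNA amount. From 100 ng, C57BL/6 splenic libraries held 873 ± 250 distinct junctions (SD, n = 3), from 500 ng 5097 ± 345 (n = 2) and from 2 ug 11118 ± 497 (n = 3). The titles call these libraries repeats, and those from 2 ug shared junctions, so they were read as repeat libraries rather than separate mice, and their SD and p describe technical repeats alone. The 12.7-fold difference between 100 ng and 2 ug gave an exact permutation p of 0.10, the smallest that 20 arrangements allow. At an equal 6961 rows the libraries held 813 ± 177, 3516 ± 184 and 5954 ± 64.5. Each junction was read 10.4 ± 0.874, 3.73 ± 0.273 and 1.38 ± 0.0241 times. From 2 ug, 71.3% to 73.9% of the junctions were seen once, against 26.8% to 31.5% from 100 and 500 ng. The number of reads thus also limited the 2 ug count. Across V segments, which are not independent replicates, the repeats correlated at r = 0.696 to 0.798 from 100 ng, 0.973 from 500 ng and 0.987 to 0.989 from 2 ug. V usage differed in 3 of 113 segments by limma (16 unadjusted), all of low share and named after their values were seen: IGHV1-56, IGHV8-6 and IGHV1-77, at 0%, 0% and 0.0451% from 100 ng and 0.102%, 0.0520% and 0.323% from 2 ug. No segment passed without the 100 ng repeat 1, either 500 ng repeat or the 2 ug repeat 2, 1 passed without the 2 ug repeat 3, and 7 and 8 passed without the 100 ng repeats 2 and 3.

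**Figure D5:**
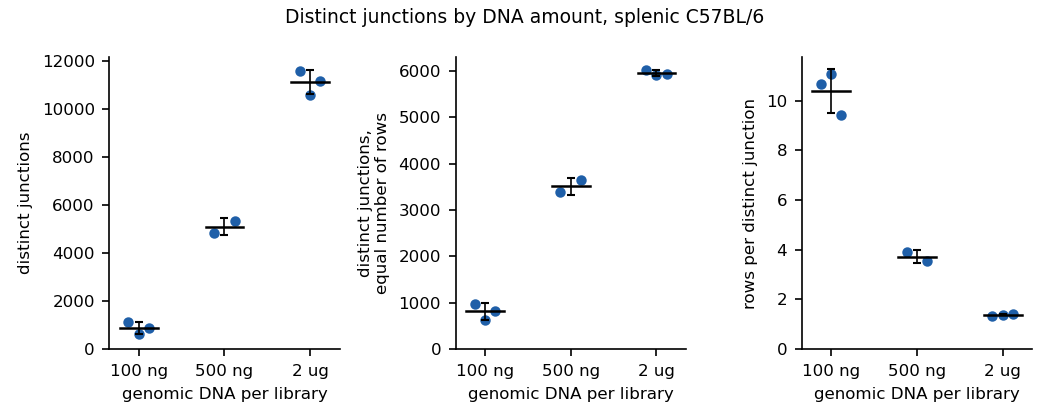
Distinct junctions, distinct junctions at an equal number of rows, and rows per distinct junction (y axes) by amount of genomic DNA per library (x axis) in splenic C57BL/6 libraries; points are libraries, bars are means and error bars SD. Means rose from 873 distinct junctions at 100 ng to 11118 at 2 ug.

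Sets of libraries made from the same kind of cells were compared with each other as controls. The C57BL/6 splenic libraries of the pro-B comparison and those of the JH4 bait set differed in 0 of 121 segments by limma (9 unadjusted), with IGHV1-26 at 4.78% and 3.60% (log2 -0.38, adjusted p = 0.27). Among segments with a mean share of at least 0.5% in a group, 6 did not overlap, where chance gives 10% of the segments of that share. These sets are not independent, since splenic replicate 1 and JH4 replicate 2 shared 31 distinct long junctions. Without JH4 replicate 3, 2 segments passed. In 129SVE, a library made with mixed bait primers correlated across V segments with the single-primer libraries at r = 0.947 to 0.978 for JH2 and 0.951 to 0.977 for JH3. Single-primer libraries correlated with one another at r = 0.952 to 0.974 and 0.941.

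For the κ light chain, V usage differed more between Jκ baits than between single and mixed primers. IGKV10-96 took 5.79% of JK1 rows (exact 95% interval 5.58% to 6.00%), 2.83% with JK2, 1.42% with JK4 and 0.675% with JK5 (0.522% to 0.858%). With mixed primers it took 6.11%, 2.92%, 1.56% and 1.08%, of which the first and the last lie outside the intervals of the single-primer libraries. IGKV6-15 ran the other way, from 0.629% (0.560% to 0.705%) with JK1 to 3.49% (3.13% to 3.87%) with JK5, and IGKV4-59 took 1.32% and 3.49%. IGKV1-135 fell from 5.99% with JK1 to 2.20% with JK5. Single and mixed libraries of the same bait correlated across V segments at a mean r of 0.981. Single-primer libraries of different baits correlated at a mean r of 0.668 (0.303 to 0.904). Single and mixed libraries of the same bait shared 990 to 1452 distinct junctions, so they may not be independent samples. These were counted without a minimum of added bases, so recurrent junctions cannot be told apart from a shared source. Each of these groups had 1 library, so no difference has a replicate check.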

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

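The tests of explanations in this part, the class-by-bait interaction, and the strain test of the DJ differences were chosen after the results were seen. The difference of selection between cell types was planned.

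The results in this part were picked out because an effect differed between groups when the difference itself was tested. In 129SVE, the log2 ratio of productive to non-productive share, read with the JH4 bait, differed between splenic and pro-B cells for 20 segments. Those lower in splenic cells included VH12-3 (-4.42), VH11-2 (-4.24), VH5-2 (-3.53), VH8-2 (-3.01), VH1-11 (-2.76), VH4-2 (-2.13), VH10-3 (-1.44), VH7-1 (-1.29), VH10-1 (-1.28) and VH8-11 (-1.24). VH3-2 (0.90), VH14-1 (1.35), VH5-12-1 (1.47) and VH1-80 (1.97) were higher. No explanation of these was weighed. For VH11-2, the productive share was 0.493% in pro-B and 0.024% in splenic cells, and the non-productive share 1.06% and 1.02%.

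The effect of the JH bait differed between productive and non-productive rows for 33 segments in 129SVE and 32 in C57BL/6. In 129SVE, VH7-1 took 1.12% ± 0.617, 0.24% ± 0.015, 0.584% ± 0.0632 and 0.579% ± 0.146 of productive rows with JH1, JH2, JH3 and JH4 (interaction adjusted p = 6.9e-07). IGHV2-9 took 0.467%, 0.0581%, 0.601% and 0.652% in C57BL/6 (interaction adjusted p = 3.5e-07). IGHV5-2 took 0.341%, 0.077%, 0.259% and 0.281% of productive and 5.30%, 6.11%, 6.69% and 5.61% of non-productive rows, and VH5-2 took 0.472%, 0.0478%, 0.429% and 0.31% of productive rows. The bait with the highest productive share was JH1 for 14, JH2 for 4, JH3 for 3 and JH4 for 11 of the 32 segments in C57BL/6, and for 12, 3, 7 and 11 of the 33 in 129SVE.

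Within this pattern, the 11-2 segment with the JH1 bait was weighed. It took 1.14% ± 0.142 of productive rows with JH1 in C57BL/6 and 0.974% ± 0.315 in 129SVE (n = 2 each), against 0.095% ± 0.0544 and 0.0774% ± 0.0405 with the other baits (n = 8 each). This 11.1-fold difference had an exact permutation p of 0.000494, the smallest of 2025 arrangements. Equal mouse numbers were read as the same animal, so the libraries of a strain stand for 3 mice and are not independent. With labels moved only among libraries of the same mouse number, the exact permutation p was 0.00694, the smallest of 144 arrangements. Better amplification of these joins by the JH1 primer would act on non-productive joins too, and there the fold was 1.14 (exact permutation p = 0.18). Exact copies of 1 junction were not the whole cause, since the fold was 4.13 with each distinct junction counted once (exact permutation p = 0.000494). Read errors in a frequent junction count as further distinct junctions and were not merged, so this test cannot exclude them. A candidate explanation that stays open is that short 11-2 to JH1 joins were favoured after rearrangement. Distinct productive joins were shorter than non-productive ones by -5.33 nt with JH1 and -2.86 nt with the other baits, and this difference of -2.48 nt missed the threshold (exact permutation p = 0.153).

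The most frequent productive 11-2 junction was the same in both JH1 libraries of a strain. In C57BL/6 it used IGHD2-5 and made up 97 of 421 and 232 of 715 rows. In 129SVE it used IGHD2-1 and made up 703 of 1488 and 140 of 592 rows, in libraries of sequencing runs B and C. All 4 had 6 bases between V and J, with 2 bases shared by the ends of V and D and 4 shared by D and J. The C57BL/6 libraries were sequenced in the same run, so reads carried between them cannot be told apart from a recurrent junction.

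For IGHD1-3, the difference between pro-B and splenic cells itself differed between the strains by 0.659 points (exact permutation p = 0.015, adjusted p = 0.13). Its share was 1.76% in pro-B and 1.36% in splenic cells of C57BL/6, and 1.62% and 1.88% in 129SVE. IGHD1-3 has no placed position in either strain, so these are shares of sequence calls and may belong to other DH segments. It did not pass after adjustment.

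The difference between DJ joins and V(D)J rows in the DST4 family differed between the strains by -3.95 points (exact permutation p = 0.000333, the smallest of 3003 arrangements; adjusted p = 0.00133) when V(D)J rows were limited to calls of DH segments with a placed position. DST4 then took 3.65% ± 1.56 of DJ joins and 6.6% ± 1.71 of V(D)J rows in C57BL/6, and 2.09% ± 1.21 and 1.08% ± 0.494 in 129SVE. This rests on that limit, since IGHD3-2 is the only DST4 segment placed in 129SVE and calls of IGHD3-1 and IGHD3-3 were left out. Over every DH call, DST4 took 8.34% ± 1.65 of V(D)J rows in C57BL/6 and 6.72% ± 1.04 in 129SVE, and was lower in DJ joins in 15 of 15 libraries. DJ joins were still assigned to placed segments alone, so IGHD3-3 calls, and in 129SVE IGHD3-1 calls, had no DJ joins to match. The lower DST4 share of DJ joins therefore does not show a change in DH use. Over every DH call the strains differed by -0.0516 points (exact permutation p = 0.914). These permutations treat libraries of the same mouse as independent. The other families did not pass under either choice.

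Splits of the same libraries into other groups of 3 were counted where both groups had 3. With 10 splits per comparison, a share under 0.05 cannot be reached. For productive rows of pro-B against splenic C57BL/6 cells, the real split gave 10 segments and the highest other split 0, so 1 of 10 splits gave as many. For non-productive rows, and for the difference of selection, all 10 splits gave 0. For the splenic libraries against the JH4 bait set, the real split gave 0 and the highest other split 1, so 10 of 10 gave at least as many.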

How the results depend on the processing

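The sequencing-run, 60 bp, non-productive V(D)J, every-DH-call, by-mouse and thinning alternatives were chosen after the data were seen; the others were planned. Results of whole comparisons were labelled the same in 116 values from alternatives other than leaving out a library, stronger in 21, weaker in 24 and moved in 1. For single values, the same means an unchanged direction and side of the threshold. For counts it means a count within a fixed fold of the main one, without a check of direction or of which members passed. The count-test alternative was planned only for files with a deposited column of counts, which these lack, and was not run on the tallied rows. Leaving out either splenic 129SVE library leaves 1 splenic library, which is then assumed to vary like the pro-B libraries, and gives no test for productive against non-productive rows of that group.

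Counts of V segments are compared with 10 (productive rows, pro-B against splenic) in C57BL/6 and 32 in 129SVE. Limma-trend gave 3 with either pseudocount in C57BL/6, and 18 and 19 in 129SVE. Distinct junctions gave 26 in C57BL/6, among them the 10. A single V allele gave 5 and the splB_JH4 libraries added to the splenic group 17. The run as a block leaves pro-B replicate 1 as the only pro-B library of the C57BL/6 contrast, so its count is not given. The added libraries share junctions with the splenic group and are not independent of it. The replicate number as a block gave 0 by limma in C57BL/6 and 19 in 129SVE. The block uses degrees of freedom, and whether the numbers pair mice is open. In C57BL/6 with the block, the log2 change was 2.70 for IGHV12-3, 2.20 for IGHV5-2, 1.96 for IGHV15-2 and -1.42 for IGHV1-52, against 2.31, 2.07, 2.06 and -1.57. For C57BL/6 non-productive rows, the run as a block again leaves pro-B replicate 1 as the only pro-B library. The count with that block, listed next, therefore supports no call of a segment. Non-productive rows in C57BL/6 (0 segments) gave 1 with no filter, 1 with a single V allele and 14 with the run as a block.

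Productive against non-productive rows in C57BL/6 pro-B cells (36) gave 63 with distinct junctions. The difference of selection in C57BL/6 (0) gave 4 when centred and 11 with distinct junctions. The cause was not tested. For the JH baits in C57BL/6 (29), limma-trend gave 15 with either pseudocount, a single V allele 17, the mouse as a block 46 (all 29 among them), productive rows 47, thinned productive rows 44, non-productive rows 0 and mice other than mouse 1 gave 2, with fewer libraries. In 129SVE (1), no filter gave 0, centring 2, distinct junctions 12, the block 7, productive rows 29, thinned productive rows 25, non-productive rows 0, mice other than mouse 1 gave 11 and the run as a block 9. For DNA amounts (3), limma-trend gave 0 with either pseudocount and the repeat number as a block 1. For the splenic libraries against the JH4 set (0), the run as a block leaves splenic replicate 3 as the only library set against the JH4 set. Its count is therefore not given.

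DH segments between pro-B and splenic cells (4) gave 0 with the replicate block, with a single DH called and in run A. DH families (3) gave 0, 1 and 0. In run A fewer libraries remain. Productive share and junction length across baits (2) gave 1 with 1 run per strain. DJ against V(D)J joins (6) gave 10 with a single DH called and 4 with signs flipped by mouse. The κ correlation of 0.981 was 0.936 with distinct junctions.

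A single V allele turned the change of IGHV5-2 from 2.07 to -0.00335 and of IGHV5-12 from 1.04 to -0.687 in C57BL/6 productive rows, and of IGHV5-2 from 0.29 to -1.47 in non-productive rows (adjusted p = 0.038). By construction this keeps few of their rows, 7.76% of the IGHV5-2 productive rows of pro-B and 17.3% of those of splenic cells. Centring turned IGHV2-2 in productive against non-productive splenic rows from -0.48 to 0.00172. VH5-2 in 129SVE non-productive rows (-0.04) ran from -0.79 without splenic replicate 2 to 0.68 without splenic replicate 3. A single DH turned IGHD2-4 in pro-B against splenic cells from -1.53 to 0.000773 points, DSP2 from -1.78 to 0.0313 and IGHD3-3 between strains from -0.407 to 0.166. In DJ against V(D)J joins it turned DFL16 from 3.03 to -14.6 points, DSP2 from -4.6 to 18.9, DQ52 and IGHD4-1 from 3.02 to -1.93, IGHD2-7 from -1.27 to 1.6, IGHD2-4 from -1.45 to 12.3 and IGHD1-1 from 3.44 to -13.1. By construction it keeps 87.6% of DFL16, 34.8% of DSP2, 49.2% of DST4 and 99.8% of DQ52 rows.

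Leaving out each library gave these ranges. Productive rows, pro-B against splenic: 0 to 25 segments in C57BL/6 (0 without splenic replicate 1) and 5 to 33 in 129SVE (5 without pro-B replicate 1). Non-productive rows: 0 to 3 in each strain. Productive against non-productive rows: 0 to 43 in pro-B (0 without replicate 2) and 73 to 96 in splenic cells of C57BL/6, and 26 to 55 in 129SVE pro-B cells. Difference of selection: 0 to 9 in C57BL/6 and 12 to 23 in 129SVE. JH baits: 19 to 38 in C57BL/6 and 0 to 8 in 129SVE. DNA amounts: 0 to 8. Splenic against JH4 set: 0 to 2. Productive share: -21.2 to -17.9 points. Junction length: 0.674 to 0.804 nt. DH between cell types: 0 to 4 segments and 0 to 3 families. Domains: 0 to 0. Across baits: 11 to 13 DH segments, 4 to 4 families, and 1 to 2 of productive share and junction length. Strains: 10 to 13 VH families, 11 to 12 DH segments, 3 to 4 DH families, 24 to 29 in all, and -1.10 to -0.493 points of productive share. DJ against V(D)J: 4 to 9, and DQ52 with JH4 in C57BL/6 8.04% to 8.74%. Distinct junctions between 100 ng and 2 ug: 10005 to 10501.

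Depth limits the low shares. Libraries of 6961 rows were the smallest, and from 100 ng of DNA 873 distinct junctions stood behind 10.4 rows each, so shares there carry far fewer rearrangements than rows.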

Other observations

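The tests of explanations in this part were chosen after the results were seen.

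With the JH1 bait, B-1-linked segments other than 11-2 were compared with the other baits in productive rows of both strains. The 12-3 segment was 3.91-fold higher with JH1 (exact permutation p = 0.00494) and 7-1 was 2.32-fold higher (exact permutation p = 0.0207), whereas 6-6 stood at 1.01-fold (exact permutation p = 0.878). The 11-1 segment took 0% of productive rows in every JH1 library and 0.0124% in C57BL/6 and 0.00308% in 129SVE with the other baits (exact permutation p = 0.146). Equal mouse numbers were read as the same animal, and with labels moved only among libraries of the same mouse number the exact permutation p was 0.0278 for 12-3 and 0.0347 for 7-1, where 144 arrangements allow 0.00694. These p were not adjusted. In non-productive rows the folds of 12-3, 7-1, 6-6 and 11-1 were 1.01, 0.947, 1.15 and 0.783. These segments were taken from the list fixed before the data were examined, and the comparison of JH1 with the other baits was chosen afterwards.

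Distinct long junctions, with at least 3 bases added on each side of D, were rarely shared between libraries. Of 820 pairs of heavy-chain libraries, 755 shared none and 19 shared more than 10. The 408 pairs across strains shared 0. Splenic C57BL/6 replicate 1 shared 31 with JH4 bait replicate 2, in sequencing runs A and E, and 28, 31 and 28 with the 2 ug repeats. Splenic 129SVE replicate 2 shared 29 with JH4 bait replicate 3, and the JH2 library of 129SVE replicate 3 shared 53 with the mixed-primer JH2 library. Pro-B and splenic C57BL/6 libraries shared up to 4.

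The productive share of pro-B cells was higher in C57BL/6 (56.7%, 68.1% and 69.9%) than in 129SVE (43.1%, 41.2% and 39.6%), by 23.6 points. Repeated rows do not explain it, since with distinct junctions counted once the difference was 21.8 points. Frame calls that differ between the references do not either, since the splenic libraries of the strains differed by 0.234 points. More cells with a completed V(D)J join in the C57BL/6 preparations stay open: DJ rows per V(D)J row were 0.98 ± 0.212 in C57BL/6 (n = 3) against 1.77 in the only 129SVE library with DJ joins. Run also cannot be told apart, as the C57BL/6 library sequenced in run A with the 129SVE libraries was the lowest of its strain, at 56.7%. A strain difference is neither shown nor excluded, since the difference between pro-B and splenic cells differed between strains by 23.4 points and missed the threshold (exact permutation p = 0.06).

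Splenic 129SVE replicate 3 held VH5-2 in 22.6% of its non-productive rows (exact 95% interval 22.1% to 23.2%), against 8.14% in replicate 2 and 8.55% to 9.59% in the JH4 bait set. Its D-proximal segments together took 56.2%, against 33.2% in replicate 2. Copies of a few junctions are excluded, as the share was 22.3% with distinct junctions counted once. Reads shared with a similar VH5 segment stay open. The share was 22.9% among rows with a single V allele, but that filter removes none of the VH5-2 rows. Pro-B cells in the preparation alone would not reach it, as the highest 129SVE pro-B library stood at 14.6%. Both splenic libraries were in run A, and no biological explanation was tested.

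The κ libraries were productive in 53.4% to 64.8% of rows and in 32.2% to 37.1% of distinct junctions.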
